A study of Homo sapiens with 4 samples.

How the data were processed

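Total RNA of 4 libraries of neural progenitor cells was sequenced, 2 controls and 2 with PRMT7 overexpression. Per the labels' protocols, the cells were differentiated from the H9 line with commercial media, RNA was isolated with Trizol and libraries were made with a VAHTS Universal V8 kit. The sources used here do not say how poly(A) RNA or ribosomal RNA was handled, or how PRMT7 was introduced. Per the submitters' processing notes, the tools were FastQC 0.12.1, fastp 0.23.1, HISAT2 2.1.0 and featureCounts 2.0.1, with GRCh38 (hg38) as the build. The annotation release, the strand setting and the handling of multi-mapped reads are not given in the sources used here. The authors deposited 1 table of raw read counts, whole numbers per Ensembl gene for the 4 libraries. How its 17785 features were chosen is not given in the sources used here, and 12 of them had 0 counts throughout. The number of table columns without a sample was 0.

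Library totals were 14467118 to 39387879 counts. Gene symbols were matched to Ensembl identifiers through a name table, and 15800 of 17785 identifiers had a symbol. Positions, gene types, transcript lengths and GC content came from GENCODE 29 on GRCh38, which held 17611 of the identifiers. That release may not be the one the counts were made with. Length and GC content were those of the longest transcript and were known for 99.3% of tested genes. Sequence copies, overlapping genes and antisense genes share reads in ways the deposited counts do not resolve.

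Groups and replicate numbers came from the sample titles, and table columns were matched by the library names in the labels. The count test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 4 libraries with TMM scaling, filterByExpr and group as the only term, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SEs were obtained from the log2 fold change and its F statistic, and 95% intervals from the matching t quantile. CPM values are counts per 1e6 of each library's total, computed here and given as mean ± SD with n = 2. The common biological coefficient of variation was 9.07%, and the median SE of a log2 fold change was 0.14. The 2 controls differed beyond sampling noise (chi-square over degrees of freedom 8.10 on genes of 10 or more counts), as did the overexpression pair (10.4), so each library counted as 1 replicate. Counting intervals and floors would cover counting error only, and 3 counts, the upper limit that a count of 0 allows, came to 0.0762 to 0.207 CPM across libraries.

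Gene lists, 41 in number, were written from general knowledge before the data were examined, together with the design, the alternatives and the rule for named genes. They cover progenitor, neuronal, glial and off-target cell types, regional identity, cell cycle, stress, interferon, signalling, matrix, RNA-quality and schizophrenia genes. Several lists share members, such as ALDOC, ID3, SOX10 and DLL3. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 40 lists. The named genes were PRMT7, then up to 12 genes in each direction with the largest change among those past the threshold, with groups not overlapping and a mean of at least 5 CPM, then up to 4 called members of each list, or the 2 of smallest p where none was called. Only PRMT7 passed, so the other named genes are members of smallest p and are reported as values. The values of 3 genes that the rule names are not reported here.

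The other settings tried were DESeq2 size factors, library totals, upper-quartile scaling, no filter, a stricter filter (1 CPM in every library of a group and a mean of 2 CPM), DESeq2 1.42.0, limma-voom, a minimum fold change of 1.2, the replicate number as a block, each library left out in turn, and for lists an estimated correlation, fry and ranks. Settings added after seeing the data were a length and GC correction (per-library natural splines with 4 degrees of freedom each), thinning of overexpression library 1 to the depth of library 2, a crossed pairing, and the list tests without PRMT7. The gene tests of edgeR, DESeq2, limma-voom and edgeR with the correction were run on simulated data drawn from the real means, library sizes and dispersions. There 67, 67 and 66 genes of at least 5 CPM were changed 1.5-fold, 2-fold and 4-fold. Among list tests only camera at the preset correlation was simulated, so the power of the estimated correlation, fry and ranks is unknown. The other settings were not simulated. With 15180 genes run, edgeR recovered 53.7%, 98.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold and made 20 false calls. With no gene changed edgeR made 0 calls. The shares recovered hold only for 67, 67 and 66 genes changed at once, since the adjustment is stricter when fewer genes pass. Camera recovered a ribosomal protein list shifted by -0.3 on the log2 scale, and called 0 lists among unchanged simulated genes, which are independent of one another, unlike real genes.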

Results

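RNA sequencing measured the transcriptome of human neural progenitor cells that overexpressed PRMT7 and of control cells. The cells were differentiated from H9, an established human embryonic stem cell line. PRMT7 is a protein arginine methyltransferase that places monomethyl marks on arginine. The study set out to learn how a raised PRMT7 level, which it connects with schizophrenia risk, acts on neural progenitors. There were 2 control libraries and 2 overexpression libraries. The gene counts summed to 16066791 and 14467118 in controls 1 and 2 and to 39387879 and 15562390 in overexpression libraries 1 and 2, so overexpression library 1 was 2.45 times as deep as the next. Of 17785 features, 15313 had enough counts to be tested, and these held 99.9% of all counts. The labels do not say whether replicates came from separate cultures, so the p-values of genes measure only the spread between these libraries, which may be technical.

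PRMT7 itself was the only gene that changed past the threshold. It rose 15.0-fold in the overexpression libraries, from 48.2 ± 0.779 to 730.1 ± 19.5 counts per 1e6 counts (CPM; mean ± SD, n = 2 per group). The gene (ENSG00000132600) lies on chromosome 16 from 68310974 to 68358563 on the plus strand of GRCh38 and is protein-coding. Its raw counts were 784 and 690 in controls 1 and 2 and 29299 and 11147 in overexpression libraries 1 and 2. The log2 fold change was 3.90 ± 0.12 (SE), with a 95% interval from 3.65 to 4.16 and an adjusted p of 6.79e-10 (edgeR quasi-likelihood test, Benjamini-Hochberg). These counts do not separate transcripts of the native locus from those of any introduced copy.

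No other gene reached an adjusted p under 0.05 in the edgeR test, so 1 gene was called higher and 0 lower. At an unadjusted p under 0.05 there were 1048 genes, 307 higher and 741 lower, where chance alone gives 765.65. DESeq2 called 2 genes, with 496 at an unadjusted p under 0.05, and limma-voom called 1, with 1130. With the replicate number as a block, edgeR called 6 genes. In the reported edgeR fit, without a block, the lowest adjusted p after PRMT7 was 0.0761. It belonged to GPR89B, a gene for a Golgi pH regulator on chromosome 1 (147928393 to 147993521). Its log2 fold change was -1.21 ± 0.18. GPR89B was singled out after its values were seen, and its counts are uncertain because it has a near-identical copy, GPR89A, at 0.63 on the same scale. The effect sizes were bounded for most genes: the 95% interval of the log2 fold change lay within a 2-fold change either way for 13758 genes (89.8%) and within 1.5-fold for 10553 (68.9%). In simulated libraries with the same depths and spread, edgeR recovered 98.5% of genes changed 2-fold and 53.7% of those changed 1.5-fold, among genes of at least 5 CPM. There 67, 67 and 66 genes were changed at once, which eases the adjustment, so these shares do not hold for a lone changed gene. In the real libraries 5 genes with a mean of at least 5 CPM changed more than 2-fold either way, and only PRMT7 was called. The libraries were close to one another: Pearson correlations of log2 CPM over genes other than PRMT7 ranged from 0.989 to 0.993, and the 2 controls correlated at 0.991. Leaving out a library raised the number of called genes, to 36 without control 1, 123 without control 2, 12 without overexpression library 1 and 134 without overexpression library 2. Each of these fits had 1 residual degree of freedom and leaned on a spread pooled over genes. The reported fit also borrowed spread from other genes, with a median prior of 11.3 degrees of freedom.

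**Figure D1:**
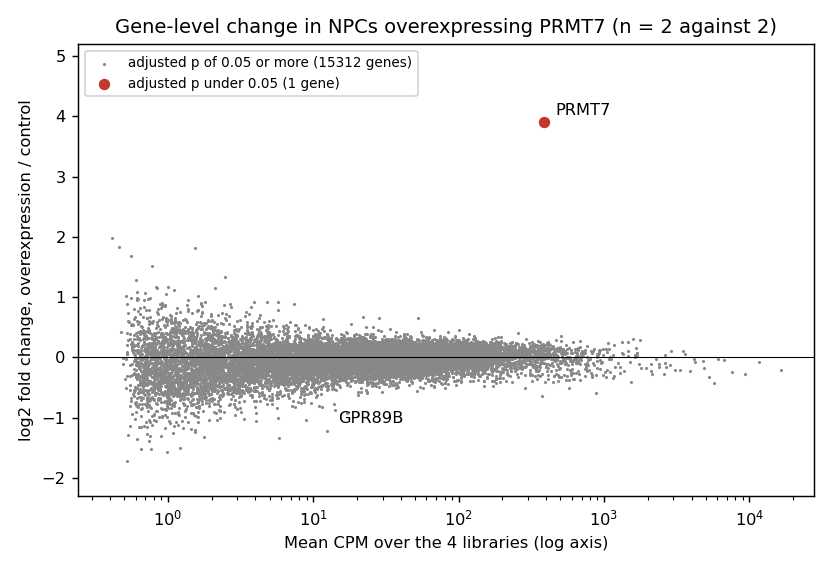
Log2 fold change (overexpression over control, y axis) against the mean CPM of the 4 libraries (x axis, log scale) for the 15313 tested genes, with 2 libraries per group. The 1 red point is PRMT7, at 3.90. GPR89B, at -1.21, did not pass the threshold.

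The lists fixed in advance were then read as groups. Values in parentheses after a gene are log2 fold changes ± SE from edgeR, and list values are medians over tested members with the Benjamini-Hochberg adjusted p of camera at a preset correlation of 0.01. In that test the gene statistics of a list are set against those of other genes. Its p therefore does not measure the spread between libraries. Camera called 11 of the 40 lists tested, 2 higher and 9 lower. None of the 11 was called with an estimated correlation (adjusted p = 0.751 for each with an estimated correlation). No member of any list other than PRMT7 passed adjustment over all genes. Adjusted over the list alone, PRMT7 and 8 other genes passed, and these are named with their lists.

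Lists for translation and oxidative metabolism were lower in the overexpression libraries. Of 77 cytosolic ribosomal protein genes, 76 had negative fold changes and 0 were called (median -0.27, adjusted p = 1.99e-12). Both overexpression libraries lay below both controls for 61 of the 77, as for RPL35 (-0.64 ± 0.17) and RPS9 (-0.51 ± 0.15). Over all 15313 tested genes this held for 2764. In either direction 36.6% of tested genes were separated, where chance gives 33.3%. The members of a list are not independent of one another. Of 50 nuclear genes of oxidative phosphorylation, 45 were negative and 0 were called (median -0.17, adjusted p = 2.25e-05). Those of smallest p were the cytochrome c oxidase subunits COX6B1 (-0.45 ± 0.12) and COX5B (-0.43 ± 0.13). Of 15 mitochondrially encoded genes 14 were negative (median -0.24, adjusted p = 0.00150). MT-ND6, a complex I subunit, was the 1 called over the list alone, at 1058 ± 181 CPM in the controls and 708 ± 13.1 CPM in the overexpression libraries (-0.60 ± 0.13). MT-ND3 had -0.38 ± 0.13. MT-ND6 lies on the opposite strand to most mitochondrial genes, and the strand setting of the counts is not given, so its reads cannot be told from antisense ones. Of 27 hypoxia and glycolysis genes 23 were negative (median -0.15, adjusted p = 0.00247), and 2 were called over the list alone: the aldolase ALDOC (-0.63 ± 0.16) and PFKFB4 (-0.49 ± 0.13), a kinase that sets fructose 2,6-bisphosphate levels. All 13 tested replication-dependent histone genes were negative and 0 were called (median -0.50, adjusted p = 2.34e-06), among them H2BC9 (-0.73 ± 0.21) and H2AC20 (-1.11 ± 0.38). The median level of the histone list was 1.82 CPM in the controls, and its members are close copies of one another, so their counts are uncertain.

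The ribosomal protein, mitochondrial and histone lists also describe RNA quality, and the first 2 varied within the control group. The mitochondrial share of counts was 8.01% and 7.36% in controls 1 and 2 and 6.63% and 6.82% in overexpression libraries 1 and 2. The ribosomal protein share was 5.44%, 4.78%, 4.09% and 4.57% in the same order. The median log2 difference of control 2 from control 1 was -0.25 for ribosomal proteins, -0.23 for mitochondrially encoded genes and -0.17 for nuclear oxidative phosphorylation, close to the values between groups. It was -0.09 for hypoxia and glycolysis and 0.01 for histones. The overexpression libraries differed as well: library 2 minus library 1 gave 0.18 for hypoxia and glycolysis, 0.17 for ribosomal proteins, 0.15 for nuclear oxidative phosphorylation, 0.01 for mitochondrially encoded genes and 0.07 for histones. Overexpression library 2 lay close to control 2 in the first 3 of these, at -0.04, -0.04 and -0.03. Both the mitochondrially encoded and the nuclear oxidative phosphorylation lists lost their call without control 1 (adjusted p = 0.153 for each, camera), and hypoxia and glycolysis lost it without overexpression library 1 (adjusted p = 0.148).

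The libraries also differed by transcript length and GC content. Among genes of at least 5 CPM, the 374 with transcripts of at most 1000 bases lay at a median of 0.23 (log2) from the gene mean in control 1 and -0.16 in overexpression library 1. Control 2 and overexpression library 2 lay at -0.01 and -0.02. For the 1114 genes with transcripts over 8000 bases the order turned over, with -0.11 in control 1 and 0.12 in overexpression library 1. For transcripts of over 65% GC, control 1 stood at 0.21 and overexpression library 1 at -0.19. After a correction for both properties, chosen after seeing the data, 10 of the 11 lists kept their call and direction. Among the 10 is the arginine methyltransferase list, whose call rests on PRMT7 itself. With PRMT7 left out, 10 lists were called before the correction and 8 after it. The ribosomal protein median went from -0.27 to -0.18. The medians went from -0.24 to -0.14 for mitochondrially encoded, from -0.39 to -0.26 for astrocyte and from -0.18 to -0.12 for forebrain genes. The MHC class I list lost its call (adjusted p = 0.0640, camera), as its median went from -0.25 (quartiles -0.48 and -0.16) to -0.14 (quartiles -0.30 and -0.03).

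**Figure D2:**
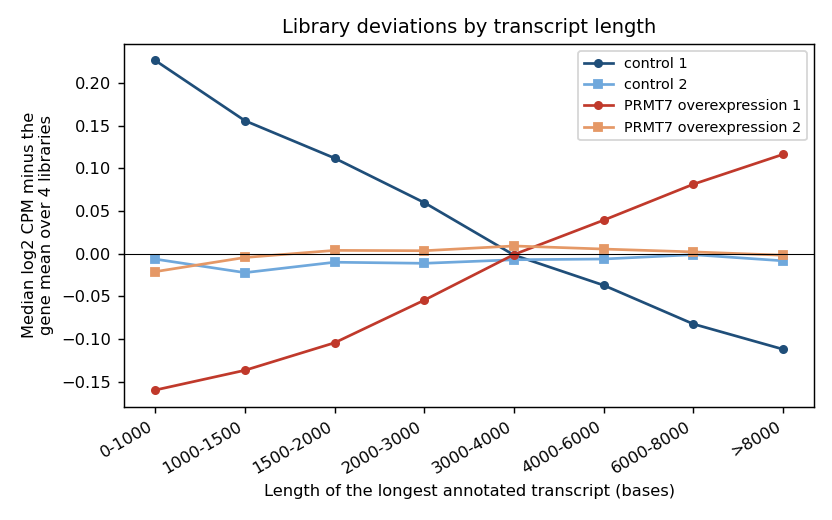
Median log2 CPM of each library minus the gene mean over the 4 libraries (y axis), for genes of at least 5 CPM grouped by the length of their longest annotated transcript (x axis, bases). Control 1 falls from 0.23 to -0.11 and overexpression library 1 climbs from -0.16 to 0.12, while control 2 and overexpression library 2 stay near 0.

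Of the other called lists, astrocyte markers were lower (median -0.39, adjusted p = 0.00193). Of 9 tested members 7 were negative, and 3 were called over the list alone: ALDOC (-0.63 ± 0.16), the BMP-responsive inhibitor ID3 (-0.43 ± 0.14) and the calcium-binding protein S100B (-0.86 ± 0.31). S100B, at 1.70 and 0.952 CPM in the 2 groups, falls outside the rule for named genes and was named after its values were seen. Among MHC class I and antigen presentation genes 6 of 8 were negative (median -0.25, adjusted p = 0.00360). CD74, the invariant chain that serves MHC class II, was the 1 called over the list alone (-0.45 ± 0.13), and the proteasome subunit PSMB10 had -0.66 ± 0.28. Neural crest markers had 11 of 12 negative values (median -0.22, adjusted p = 0.0248), with TFAP2A (-0.38 ± 0.17) and SOX10 (-0.40 ± 0.18) of smallest p. Forebrain identity genes had 14 of 17 negative values (median -0.18, adjusted p = 0.0266), with the eye-field factor RAX (-1.08 ± 0.41) and the interneuron factor DLX2 (-0.68 ± 0.30) of smallest p. RAX was at only 1.46 CPM in the controls and 0.800 CPM in the overexpression libraries. DLX2 was at 4.34 and 9.51 CPM in overexpression libraries 1 and 2 and at 8.34 and 12.5 CPM in controls 1 and 2, so its groups overlapped. The medians of overexpression library 2 minus library 1 were 0.25 for neural crest and 0.20 for forebrain genes, and for forebrain genes overexpression library 2 minus control 1 gave 0.01. Unfolded protein and integrated stress response genes were higher, with 22 of 28 positive (median 0.14, adjusted p = 0.00360). Its medians within groups were larger, at -0.21 for control 2 minus control 1 and -0.22 for overexpression library 2 minus library 1, and overexpression library 2 minus control 1 gave -0.05. The members of smallest p went in opposite directions, DDIT4 (-0.32 ± 0.12) and the asparagine synthetase gene ASNS (0.49 ± 0.18). HSPA5, the main chaperone of the endoplasmic reticulum, falls outside the rule for named genes and was named after its values were seen (0.31 ± 0.13). The arginine methyltransferase list was called higher (median 0.04, adjusted p = 0.0248), but without PRMT7 its adjusted p was 0.26. PRMT7 was its 1 called member, and the median of its 12 genes was 0.04. The astrocyte, MHC class I, ribosomal protein and histone lists kept their calls whichever library was left out. Without overexpression library 1 the neural crest, forebrain and stress response lists had adjusted p of 0.979, 0.617 and 0.498 (camera), and without control 2 of 0.263, 0.269 and 0.799. The neural crest list also lost its call without control 1 (0.0522), and the arginine methyltransferase list without control 2 (0.106) and without overexpression library 2 (0.0824).

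**Figure D3:**
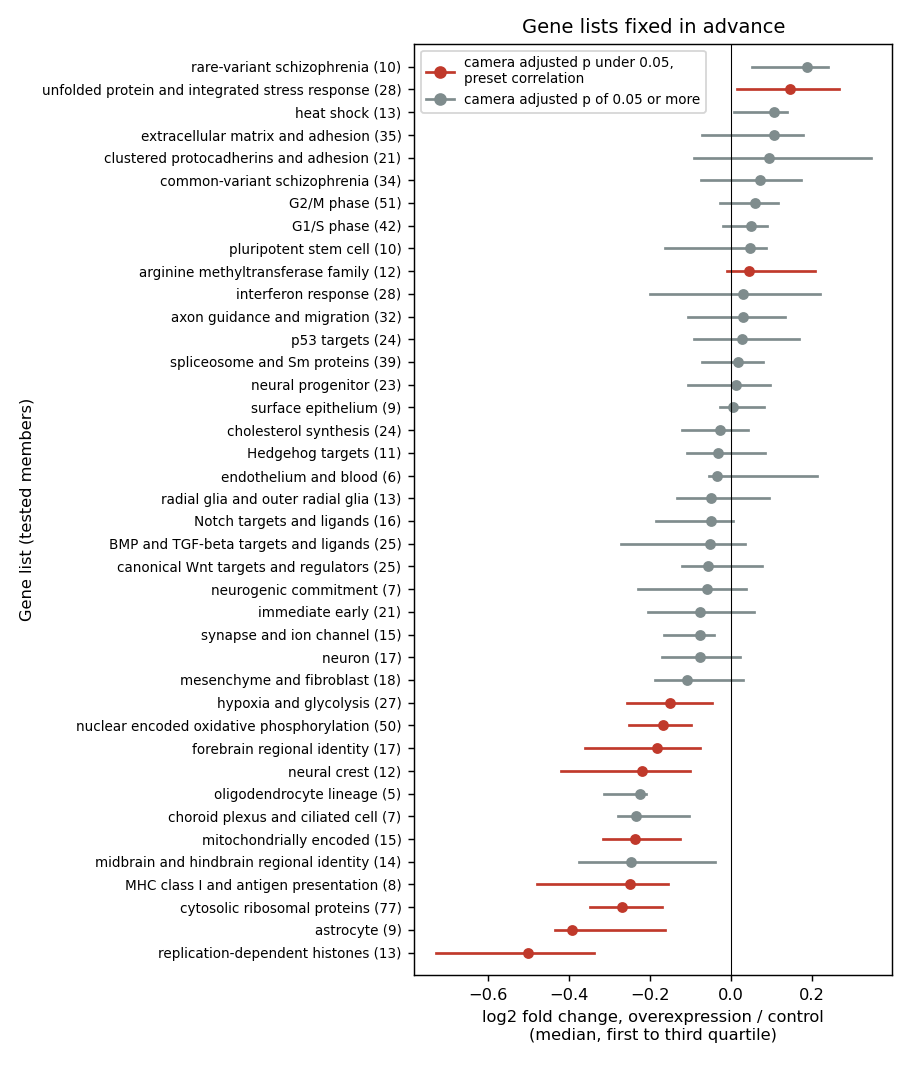
Log2 fold change (overexpression over control, x axis) of each list fixed in advance (y axis, with the number of tested members in parentheses): the points are medians and the lines run from the first to the third quartile. The 11 red lists were called by camera at a preset correlation of 0.01, and none of them with an estimated correlation; the lowest median is -0.50, for replication-dependent histones.

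The markers of the progenitor state did not pass as a list (median 0.01, adjusted p = 0.584), and 0 of 23 were called. Of 3 familiar members chosen after their values were seen, the stem cell factor SOX2 was at 195 ± 9.12 CPM in the controls and 198 ± 0.386 CPM in the overexpression libraries, and the 95% interval of its log2 fold change ran from -0.21 to 0.23. For NES, the intermediate filament nestin, the values were 636 ± 94.7 CPM in the controls and 725 ± 11.7 CPM in the overexpression libraries. The cortical progenitor factor PAX6 (0.07 ± 0.11) was the third. The members of smallest p were PLAGL1 (0.24 ± 0.14) and the cadherin CDH2 (0.17 ± 0.11). Upper-quartile scaling turned the sign of this list's median, to -0.0017, and library totals put it at 0.03. Radial glia markers (median -0.05, adjusted p = 0.704) held 1 gene called over the list alone, TTYH1 (-0.55 ± 0.14), followed by MOXD1 (-0.39 ± 0.27). Neurogenic commitment genes did not pass (median -0.06, adjusted p = 0.411), with DLL3 (-0.64 ± 0.23) and HES6 (-0.24 ± 0.16) of smallest p. Neuronal genes did not pass (median -0.08, adjusted p = 0.470), with TAGLN3 (-0.41 ± 0.13) and SYT1 (0.27 ± 0.13). Synapse and ion channel genes did not pass (median -0.08, adjusted p = 0.327), with NLGN3 (-0.35 ± 0.19) among those of smallest p. Axon guidance and migration genes did not pass (median 0.03, adjusted p = 0.704), with ROBO3 (-0.48 ± 0.16) and UNC5D (0.31 ± 0.12), and a mean of opposite sign to the median (-0.01).

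The remaining marker lists of cell types and regions did not pass either. Oligodendrocyte lineage genes had 5 of 5 negative values (median -0.22, adjusted p = 0.0523), led by SOX10 (-0.40 ± 0.18). The list was called lower without control 1 (adjusted p = 0.0159, camera), without overexpression library 2 (0.0481) and with overexpression library 1 thinned (0.0407). EN2 (-1.50 ± 0.47) and IRX2 (-0.38 ± 0.16) led the midbrain and hindbrain identity genes. EN2 was at only 1.69 CPM in the controls and 0.724 CPM in the overexpression libraries. The midbrain and hindbrain list had 12 of 14 negative values (median -0.25, adjusted p = 0.0866). Overexpression library 1 carried this value: the medians of overexpression library 2 against controls 1 and 2 were 0.11 and -0.05, and the direction turned without library 1 (adjusted p = 0.534, camera). The list was called lower without overexpression library 2 (4.88e-06) and without control 1 (0.0255), and had 0.544 after the length and GC correction. Mesenchyme and fibroblast genes (median -0.11, adjusted p = 0.179) were led by S100A4 (-0.41 ± 0.14) and COL6A2 (-0.29 ± 0.11). Pluripotent stem cell genes (median 0.05, adjusted p = 0.633) were led by L1TD1 (0.12 ± 0.11) and POU5F1 (-0.17 ± 0.16), and their mean was of opposite sign to the median (-0.03). Surface epithelium genes (median 0.00, adjusted p = 0.550) were led by GRHL3 (0.77 ± 0.35) and TP63 (0.91 ± 0.51). TP63 was at 0.685 and 1.87 CPM in controls 1 and 2 and at 3.33 and 0.900 CPM in overexpression libraries 1 and 2. The epithelial median was of opposite sign under upper-quartile scaling, at -0.0095, and the list was called higher without control 1 (adjusted p = 0.0338, camera). Endothelium and blood genes had a negative median, a positive mean (0.05) and an upward camera direction (median -0.03, adjusted p = 0.677), led by TEK (0.34 ± 0.14) and KDR (0.29 ± 0.14). Choroid plexus and ciliated cell genes (median -0.24, adjusted p = 0.233) were led by CCDC153 (-0.68 ± 0.43) and PIFO (-0.31 ± 0.25), and were called lower without overexpression library 2 (0.0481). The mesendoderm list had 4 tested members, too few for the list test, among them CXCR4 (-0.40 ± 0.17) and AFP (-0.39 ± 0.33).

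The lists of cell cycle, p53, interferon, heat shock, immediate early, cholesterol and spliceosome genes did not pass. G1/S genes had 28 of 42 positive values (median 0.05, adjusted p = 0.153), with CASP8AP2 (0.25 ± 0.13) and CLSPN (0.21 ± 0.11) of smallest p. G2/M genes had 34 of 51 positive values (median 0.06, adjusted p = 0.233), although the members of smallest p were both negative, the chromosomal passenger genes BIRC5 (-0.25 ± 0.11) and AURKB (-0.27 ± 0.12). Without control 2 both cell cycle lists were called higher (adjusted p = 0.0297 for G1/S and 0.0490 for G2/M, camera). The p53 targets (median 0.03, adjusted p = 0.274) were led by FAS (0.38 ± 0.14) and RRM2B (0.30 ± 0.14). Interferon response genes (median 0.03, adjusted p = 0.873) were led by BST2 (-0.53 ± 0.18) and IFI44 (0.69 ± 0.27), and their mean was -0.00203. Heat shock genes had a positive median (median 0.11, adjusted p = 0.406), while their members of smallest p were HSPB1 (-0.43 ± 0.14) and HSPE1 (-0.25 ± 0.13). Immediate early genes (median -0.08, adjusted p = 0.372) held 1 gene called over the list alone, FOS (-0.80 ± 0.19), followed by CCN1 (0.23 ± 0.12). Cholesterol synthesis genes (median -0.03, adjusted p = 0.677) included MVK (-0.28 ± 0.13) among those of smallest p. Spliceosome and Sm protein genes (median 0.02, adjusted p = 0.698) were led by SNRPA (-0.38 ± 0.11) and SNRPD2 (-0.28 ± 0.11), and their mean was -0.02, opposite in sign to the median.

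Signalling and matrix lists did not pass. Wnt genes (median -0.06, adjusted p = 0.633) were led by APCDD1 (-0.39 ± 0.15) and FZD5 (0.39 ± 0.15). BMP and TGF-beta genes (median -0.05, adjusted p = 0.274) were led by ID3 (-0.43 ± 0.14) and GREM1 (0.31 ± 0.12). Hedgehog genes had a negative median and mean and an upward camera direction (median -0.03, adjusted p = 0.855), led by PTCH1 (0.27 ± 0.13) and CDON (0.27 ± 0.15). Notch genes had 12 of 16 negative values (median -0.05, adjusted p = 0.265), led by HEY2 (-0.89 ± 0.29) and DLL3 (-0.64 ± 0.23). Extracellular matrix and adhesion genes (median 0.11, adjusted p = 0.105) were led by ITGA1 (0.56 ± 0.17) and COL11A1 (0.35 ± 0.14), and were called higher without overexpression library 2 (adjusted p = 0.0233, camera). Clustered protocadherins (median 0.09, adjusted p = 0.0539) were led by PCDHGA3 (0.50 ± 0.21) and PCDHA12 (0.62 ± 0.28), whose reads may be split among near-identical neighbours. This list was called higher without control 2 (0.00470) and without overexpression library 2 (0.0233).

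The schizophrenia gene lists, which bear on the question of the study, did not pass in the reported test. Of 10 tested genes hit by rare variants 9 had positive fold changes (median 0.19, adjusted p = 0.0511). The rare-variant list was called higher by ranks of genes (adjusted p = 0.0293) and with overexpression library 1 thinned (0.0456). After the length and GC correction it had an adjusted p of 0.200 (camera), and its median went from 0.19 to 0.09. With a library left out its adjusted p ran from 0.0521 to 0.491. The exception was also the member of smallest p, the calcium channel gene CACNA1G (-0.65 ± 0.26), followed by TRIO (0.24 ± 0.10), a guanine nucleotide exchange factor. Of 34 tested genes near common risk variants 20 were positive (median 0.07, adjusted p = 0.239), with NT5C2 (0.40 ± 0.14) and MAPK3 (-0.26 ± 0.12) of smallest p. In both lists 0 genes were called, over all genes or over the list alone.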

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

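The length and GC correction, the thinning, the crossed pairing and the list tests without PRMT7 were chosen after seeing the data; the other alternatives were planned. PRMT7 stayed called under every alternative, with a log2 fold change from 3.86 to 3.97. The number of genes called, 1 in the reported fit, was also 1 with DESeq2 size factors, the stricter filter, limma-voom and a minimum fold change of 1.2. It was 2 with library totals, upper-quartile scaling, no filter, DESeq2, the length and GC correction and the thinned library, the second gene being GPR89B each time. It ranged from 12 to 134 with a library left out. There the moderation toward the trend over genes was complete, or nearly so (prior degrees of freedom 179 without overexpression library 1), so a lone library was assumed to vary as the remaining pair did. Nothing in the labels says that a replicate number marks a shared batch. The library names do share a prefix, H1 or H2, between control and overexpression libraries of the same number. Same-numbered libraries deviated from their group means with a correlation of -0.20. With the replicate number as a block, 6 genes were called: PRMT7, GPR89B, RN7SL1, NDUFA4L2, LUM and EIF3CL, named after their values were seen. A crossed pairing, which no label supports and the library names go against, called 945 genes, 330 higher and 615 lower. The count of 1 thus depends on whether and how the libraries pair, which the labels do not state. Both blocked fits left 1 residual degree of freedom and leaned on a spread pooled over genes. Prior degrees of freedom were infinite for the replicate block and 90.1 for the crossed pairing. The crossed pairing was picked after seeing the data, so its 945 calls may be inflated and do not show a response. The number of lists called, 11 in the reported test, was 0 with an estimated correlation and 0 with fry, and 7 to 15 with a library left out, the 7 being without overexpression library 1. It was 10 to 14 with library totals, the replicate block, the length and GC correction, the thinned library, ranks and PRMT7 left out, and no called list changed direction in any of these. The block kept the 11 and also called the oligodendrocyte (adjusted p = 0.0398, camera) and midbrain and hindbrain (0.00296) lists lower and the clustered protocadherin list higher (0.0398). For the other scalings and limma-voom only list medians were computed, and camera was not rerun. The length and GC correction turned the sign of several uncalled medians. Notch went from -0.05 to 0.04, neurogenic commitment from -0.06 to 0.02 and endothelium and blood from -0.03 to 0.10. Axon guidance went from 0.03 to -0.06 and immediate early from -0.08 to 0.01, both with a turned camera direction. Radial glia (0.0032), pluripotent (-0.013) and spliceosome (-0.0099) medians turned too, the last also in camera direction. Choroid plexus went from -0.24 to -0.05. For the 79 other named genes, 1043 of 1097 alternative values kept their direction and their side of the threshold, 49 became called, 5 changed sign without being called and 0 called values reversed. At this depth and with 2 libraries per group, 53.7% of genes changed 1.5-fold were recovered in a simulation with many genes changed at once. Of the 29 lists not called, 14 changed direction and 8 became called with some library left out.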

Other observations

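The tests of the near-identical gene copies and of the count of genes in other splits were chosen after the values they use had been seen; the corrected and thinned tests were also added after the trends were seen, but their criteria were written before their results. Beyond the comparison, the libraries give a picture of the culture. Alongside progenitor genes, some genes known from pluripotent cells were expressed in both groups, chosen here for their levels. Of the 17 genes of the pluripotent list, 10 had enough counts to be tested. LIN28A, an RNA-binding protein that blocks let-7 maturation, was at 1012 ± 18.1 CPM in the controls and 1086 ± 40.3 CPM in the overexpression libraries (mean ± SD, n = 2). LIN28B was at 203 ± 22.3 CPM in the controls and 219 ± 15.0 CPM in the overexpression libraries, and DPPA4 at 138 ± 10.8 CPM in the controls and 141 ± 4.60 CPM in the overexpression libraries. POU5F1 was at 44.1 ± 10.6 CPM in the controls and 39.9 ± 3.95 CPM in the overexpression libraries, although reads of its many processed copies can be counted with it. None of these was called between groups.

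The neuron list had a median level of 25.4 CPM over its 17 tested members in the controls, with wide differences among them. DCX, a migrating-neuron marker, was at 4.10 ± 1.04 CPM in the controls and 3.97 ± 0.558 CPM in the overexpression libraries. The collagen gene COL1A1 was at 155 ± 25.4 CPM in the controls and 148 ± 4.49 CPM in the overexpression libraries. The gap junction gene GJA1, shared by radial glia and astrocytes, was at 504 ± 36.3 CPM in the controls and 529 ± 37.8 CPM in the overexpression libraries, and the VEGF receptor gene KDR at 115 ± 2.88 CPM in the controls and 142 ± 35.7 CPM in the overexpression libraries. LUM, a matrix proteoglycan gene, differed between libraries within each group, at 17.8 ± 7.34 CPM in the controls and 10.3 ± 6.54 CPM in the overexpression libraries. These bulk values do not say which cells carried the transcripts.

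The first pattern is the set of 11 lists called at a preset correlation. The arginine methyltransferase list is among them and rests on PRMT7 itself, so its kept calls carry no weight. After correction for transcript length and GC content 10 lists kept call and direction. These trends were thus not shown to account for the whole pattern. A kept call is weak evidence, since the split by replicate number, which follows no group, still called 6 lists after correction. With overexpression library 1 thinned, 11 kept call and direction. Thinning leaves the expected share of each gene unchanged, so it could hardly have removed a call. It does not test a difference that came with the deeper library. After correction both overexpression libraries lay beyond both controls in the direction of the call for 9 of the 11 lists, but the lists had been picked for differing between these groups, so this decides nothing, and a response to PRMT7 stays open. With 4 libraries there are 3 splits, and 1 of them, the real one, called as many lists (10 with PRMT7 left out, against 8 for the split by replicate number and 5 for the crossed split), so no share under 0.05 can be reached. After correction these counts were 8, 6 and 2. Correlated members stay open as an explanation, since 0 lists were called with an estimated correlation and the other splits called lists too. Whether the estimated-correlation test could recover such shifts from 4 libraries was not tested.

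The second pattern is the excess of genes at an unadjusted p under 0.05 in the reported fit. The excess was also present in edgeR with the other scalings and in limma-voom (1053 to 1144 of 15313 genes). It was absent with the replicate number as a block (644 of 15313) and with DESeq2 (496 of 17773). With PRMT7 left out, 1036 genes passed in the real split, 1710 in the split that puts control 1 with overexpression library 2, and 173 in the split by replicate number, where chance gives 765.6. So 2 of the 3 splits gave a count as large as the real one, the real one included, and the highest came from a split that follows no group. After the length and GC correction the crossed split fell to 1079 genes while the real split stood at 1091. These trends may account for part of the excess in the crossed split. In the real split the correction did not lower the count. It also changes the spread within groups, so a kept count cannot exclude these trends there. No share under 0.05 can be reached with 3 splits.

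The third pattern is the opposite change of near-identical gene copies. GPR89B made up 66.0% and 66.2% of the summed GPR89A and GPR89B counts in controls 1 and 2 and 47.3% and 24.3% in overexpression libraries 1 and 2. The summed counts gave a log2 fold change of -0.30 ± 0.17 (95% interval -0.66 to 0.06), so reads shared between the copies may account for part or all of the GPR89B value, and a real decrease stays open. EIF3CL, at -0.92, and EIF3C, at 0.65, summed to 0.27 ± 0.11 (95% interval 0.04 to 0.50), an interval that leaves out 0, so reads moving between copies may be part of this pattern but were not shown to be all of it. EIF3CL was 23.9% of its pair in control 1 and 46.4% in control 2, a difference within 1 group. No biological explanation was tested for either pair.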
